A study of Mus musculus with 21 samples.

How the data were processed

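Gene expression was measured by RNA sequencing in the livers of 21 wild-type mice. The RNA was total RNA purified with an RNeasy kit, and the libraries were stranded total RNA libraries, per the labels. The labels place 5 livers in a chow group, 8 in a group after 8 weeks of CDA-HFD and 8 in a group after 16 weeks of CDA-HFD. They give no batch, sex or pairing, so no such term entered any model. Replicate numbers follow the order in which the samples are listed.

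The authors deposited raw counts per Ensembl gene, without normalization, for each of 52636 gene IDs. The genome build was GRCm38 per the submitters' processing notes. The aligner, the counting program and the annotation release are not given in the sources used here. The counts held per sample were identical to the columns of the table for the whole series in 21 of 21 samples. Gene symbols and coordinates came from GENCODE M21, which gave a symbol for 52403 of the IDs (99.56%).

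Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15 with matplotlib 3.10.9. Genes with low counts were removed with filterByExpr by group, which left 17104 genes holding 99.961% of the counts. Libraries were scaled with TMM factors. All 21 libraries entered 1 quasi-likelihood fit in edgeR (glmQLFit and glmQLFTest), and 3 contrasts were tested: 8 weeks of CDA-HFD against chow, 16 weeks of CDA-HFD against chow, and 16 against 8 weeks of CDA-HFD. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM values are counts scaled to TMM-adjusted library sizes.

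Before the data were examined, 39 gene lists with 503 genes, the tests, the alternatives and the rule for naming genes were fixed. Each list was tested with camera (limma) with a preset inter-gene correlation of 0.01, adjusted over the 39 lists, and again with a correlation estimated from the data. Beside each list stands the number of its measured members that were called, both over all genes tested and adjusted over the list alone. The rule names 16 panel genes, of which 1 is not reported here, and for each comparison the 6 genes with the largest rise and the 6 with the largest fall. The latter had to be called, to reach 5 CPM in the higher group, to have libraries that do not overlap between the groups, and to carry an assigned symbol. Up to 2 called members of each list with the largest change serve as examples. Any other gene or marker set is named as chosen after its values were seen.

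A gene without counts in a group was set to a floor of 3 counts over the group, and a fold against it is a lower bound. For a gene with 1 to 3 counts in a group, the pooled ratio is given with its exact 95% interval. Such intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

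The procedure was tested on simulated libraries of these sizes with 1 spread per gene for all groups. Among 17104 simulated genes, 56.7% of the 67 genes changed 2-fold were called at 8 weeks against chow, 50.7% at 16 weeks against chow and 55.2% at 16 against 8 weeks. For genes changed 4-fold the shares were 86.4%, 83.3% and 90.9%, and for genes changed 1.5-fold they were 11.9%, 10.4% and 25.4%. Unchanged genes were called in 7, 5 and 6 cases. A simulated list of 15 changed genes was called in each comparison and 0 of 38 unchanged lists were called by camera. Simulated genes were drawn independently, which cannot show how often camera calls unchanged lists whose members vary together. Nor was a library like 8-week replicate 3 simulated, so these shares may not hold here.

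The alternatives fixed in advance were DESeq2 size factors, no filter on low counts, a filter at a mean of 1 CPM, the DESeq2 Wald test, a fit of only the 2 groups compared, the 20 most abundant genes left out, and each of the 21 libraries left out in turn. The alternatives added after the values were seen were replicates 3, 4 and 5 of the 8-week group left out together, the 5 libraries highest in squamous epithelium transcripts left out together, scaling by total counts alone, and an estimated correlation without replicate 3 of the 8-week group. Group labels were also exchanged in 100 splits per comparison. Relations between list scores were tested within each CDA-HFD group with exact two-sided permutation tests. No library was left out of the reported values. No chow group was sampled beside the 16-week livers, so that age and time on the diet cannot be separated there.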

Results

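RNA counts were available for the livers of 21 wild-type mice in 3 groups. The 5 chow livers were taken after 8 weeks on normal chow, a point that the labels denote week 0. The other livers came from mice fed CDA-HFD, a choline-deficient, amino acid-defined diet rich in fat that is used to produce steatohepatitis with fibrosis in mice. Of these, 8 were taken after 8 weeks and 8 after 16 weeks on the diet. Total counts per library ran from 33522456 to 42586342 on chow, from 29037525 to 45868842 after 8 weeks and from 35254088 to 48901145 after 16 weeks of CDA-HFD. Between 19453 and 23505 genes had at least 1 count in a library. Gene levels are given as mean CPM (counts scaled to library size) ± SD, over 5 chow, 8 8-week and 8 16-week libraries. Xist stayed at or under 0.201 CPM in all 21 libraries and Ddx3y, a gene of the Y chromosome, was present in each, so all animals had the transcripts of males.

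Several libraries held transcripts of other tissues. Transcripts of squamous epithelium (10 genes, Krt13 and Krt4 among them, a set chosen after the values were seen) summed to 0.1103 to 0.6308 CPM on chow, so that no member reached 1 CPM in a chow liver. Their sum was 1901 CPM in replicate 3 and 316.9 CPM in replicate 6 of the 8-week group, and 279.4, 167.4 and 82.61 CPM in replicates 1, 7 and 4 of the 16-week group. Exocrine pancreas transcripts summed to 7907 CPM in replicate 4 and 347.9 CPM in replicate 5 of the 8-week group. Replicate 3 of the 8-week group stood apart in other measures too. Its log2 CPM correlated with the other 7 libraries of its group at r between 0.813 and 0.883 across genes, where those 7 correlated with each other at 0.948 to 0.991. Mitochondrial genes made up 0.2495% of its counts, against 2.224 to 3.179% in the other CDA-HFD libraries. It also held 2992 CPM of skeletal muscle transcripts (a set likewise chosen after the values were seen) and 416.8 CPM of fat tissue transcripts. Muscle transcripts summed to 335.1 CPM in replicate 6 of the 8-week group and to 396.2, 371.3 and 225.8 CPM in replicates 1, 4 and 7 of the 16-week group. A chow liver held them too, with 389 CPM of muscle and 32.45 CPM of fat transcripts in replicate 5.

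**Figure D1:**
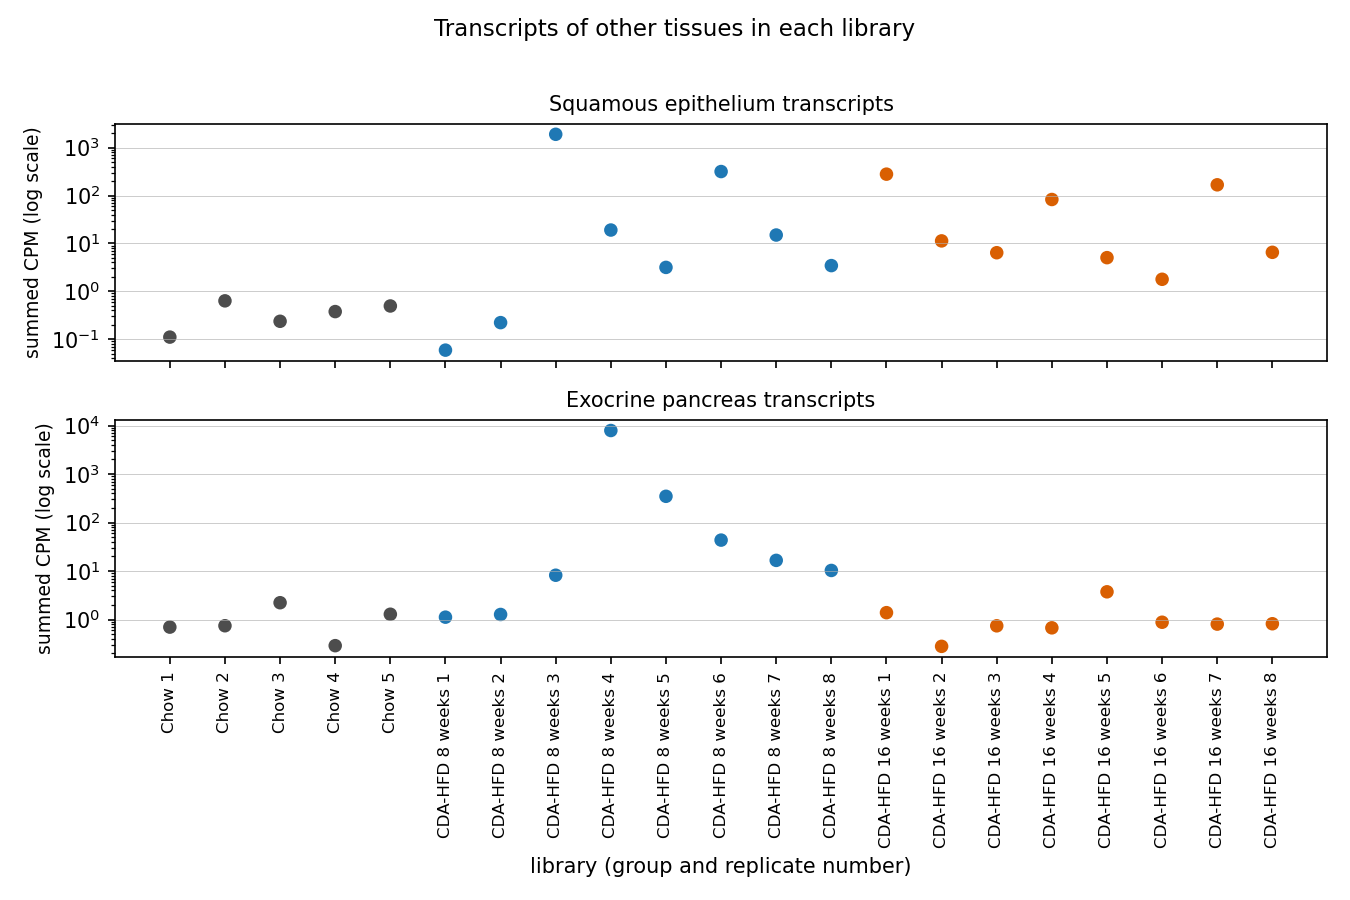
Summed CPM (log axis) of squamous epithelium and exocrine pancreas transcripts, with 1 point per library in the chow, 8-week and 16-week groups. Replicate 3 of the 8-week group reached 1901 CPM of squamous transcripts and replicate 4 of that group 7907 CPM of pancreas transcripts.

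The first comparison set 8 weeks of CDA-HFD against the chow livers, and asks which transcripts differ with the diet. The chow livers are given as 8 weeks on chow but are labelled week 0, so an equal age is not shown. After 8 weeks of CDA-HFD, the livers held more transcripts of matrix genes, of scar-associated macrophages, of T cells and chemokines and of the cell cycle, and fewer of fatty acid synthesis, amino acid breakdown and male-biased liver genes. These group results come from camera with a preset correlation, and 0 of the 39 lists passed with an estimated one. Col1a1 (ENSMUSG00000001506, GRCm38 chromosome 11, 94936224 to 94953042), which encodes a chain of type I collagen, rose 15.7-fold from 12.1 ± 3.19 CPM (SD, n = 5) to 189.7 ± 65.5 CPM (SD, n = 8; edgeR adjusted p = 4.47e-09). Gpnmb (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), a glycoprotein of lipid-laden macrophages, rose 1577-fold from 0.357 ± 0.21 to 553 ± 271 CPM (edgeR adjusted p = 1.25e-10). Scd1 (ENSMUSG00000037071, chromosome 19, 44394455 to 44407879), the desaturase that makes monounsaturated fatty acids, fell from 8978 ± 1417 to 143 ± 58.9 CPM (log2 change -5.98, edgeR adjusted p = 3.68e-10). For each of these 3 genes every CDA-HFD library lay on 1 side of every chow library.

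Matrix genes rose together at 8 weeks. Among the collagens 13 of 15 rose and 0 fell (median log2 change 1.66, camera adjusted p = 6.15e-08, and adjusted p = 0.194 with an estimated correlation). Col1a2, the partner chain of Col1a1, rose from 19.5 ± 4.22 to 173 ± 48.5 CPM, and Col3a1 (ENSMUSG00000026043, chromosome 1, 45311538 to 45349706) rose from 52.96 ± 12.2 to 394 ± 136 CPM (log2 change 2.89, edgeR adjusted p = 3.02e-08). Of 17 genes of matrix crosslinking and protease control, 15 rose and 1 fell (median 1.99, camera adjusted p = 1.14e-06, and adjusted p = 0.176 with an estimated correlation). Lox, which crosslinks collagen, rose from 0.668 ± 0.2 to 5.77 ± 2.27 CPM (log2 change 3.11), and Mmp13, a collagenase, rose from 0.282 ± 0.0653 to 6.48 ± 2.23 CPM. Timp1, an inhibitor of matrix proteases, rose by a log2 change of 7.18 (adjusted p = 1.75e-06), or 6.17 without replicate 3 of the 8-week group. Matricellular proteins, elastic fibres and proteoglycans rose in 15 of 16 cases and fell in 1 (median 1.72, camera adjusted p = 9.03e-06, and adjusted p = 0.192 with an estimated correlation). Tnc, the matrix glycoprotein tenascin C, went from 1.71 ± 0.441 to 12.4 ± 5.47 CPM. Of 13 markers of activated stellate cells and myofibroblasts, the main matrix-producing cells of the liver, 12 rose (median 2.16, camera adjusted p = 9.45e-05, and adjusted p = 0.23 with an estimated correlation). Vim, an intermediate filament, rose from 27.6 ± 7.53 to 219.8 ± 101 CPM, and Acta2, the smooth muscle actin of myofibroblasts, rose by 2.49 on the log2 scale (adjusted p = 0.00084), or by 1.70 without replicate 3 of the 8-week group. Quiescent stellate cell markers (3 rose, 1 fell, 7 not called, camera adjusted p = 0.837) and TGF-beta pathway genes (5 rose, 2 fell, 7 not called, camera adjusted p = 0.846) did not pass as groups. Tgfb1, a profibrotic cytokine, rose within that pathway from 10.5 ± 1.61 to 37.8 ± 8.69 CPM.

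Markers of inflammatory cells were higher as well. All 13 scar-associated macrophage markers rose (median 4.67, camera adjusted p = 4.86e-11, and adjusted p = 0.172 with an estimated correlation), among them Mmp12, the macrophage elastase, from 0.359 ± 0.143 to 292 ± 122 CPM (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499). Trem2 (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147), a lipid receptor of macrophages, rose by 7.09 on the log2 scale (adjusted p = 1.36e-06), or by 6.02 without replicate 3 of the 8-week group. Of 10 resident Kupffer cell markers 7 rose and 1, C6, fell (median 1.07, camera adjusted p = 0.0398, and adjusted p = 0.473 with an estimated correlation). The scavenger receptor Marco (ENSMUSG00000026390, chromosome 1, 120474538 to 120505024) rose from 10.6 ± 1.55 to 139 ± 70.8 CPM, and Clec4f (ENSMUSG00000014542, chromosome 6, 83644542 to 83656187), a lectin of Kupffer cells, rose 2.07-fold from 136 ± 15.5 to 281 ± 136 CPM (adjusted p = 0.00753). The call of Clec4f was lost without 8-week replicates 3, 4 and 5 (0.67, adjusted p = 0.0552, range 0.000871 to 0.0552 over the alternatives). The Kupffer list did not pass without chow replicate 1 (0.0548) or 8-week replicate 1, 5 or 8 (0.0748, 0.063 and 0.0531, range 0.0183 to 0.624). Chemokines and cytokines rose in 16 of 17 cases (median 2.90, camera adjusted p = 5.11e-09, and adjusted p = 0.125 with an estimated correlation). Ccl2, which attracts monocytes, rose from 1.19 ± 0.577 to 14.6 ± 7.24 CPM (log2 change 3.60, adjusted p = 4.08e-07), Ccl5 rose from 1.17 ± 0.203 to 21.2 ± 19.5 CPM, and Ccl20, without a count on chow, was at least 13.7-fold higher. T and NK cell markers (13 of 14 rose, 1 fell, camera adjusted p = 0.000304, and adjusted p = 0.23 with an estimated correlation) included Cd8b1, a chain of the CD8 receptor, at 0.181 ± 0.111 and 3.81 ± 3.25 CPM. Neutrophil markers (8 of 9 rose, camera adjusted p = 0.00372, and adjusted p = 0.378 with an estimated correlation) and dendritic cell markers (6 of 8 rose, camera adjusted p = 0.00535, and adjusted p = 0.176 with an estimated correlation) also passed. Ltf, lactotransferrin of neutrophil granules, rose by 3.39 on the log2 scale and Ccr7, a homing receptor, by 2.93. Interferon-stimulated genes rose in 12 of 13 cases (camera adjusted p = 1.29e-05, and adjusted p = 0.172 with an estimated correlation), with Usp18 at 8.07 ± 1.02 and 34.5 ± 12.2 CPM. B and plasma cell markers (5 of 10 rose, camera adjusted p = 0.0751) and acute phase proteins (5 of 14 rose, camera adjusted p = 0.154) did not pass as groups. The acute phase list passed without chow replicate 3 or 5 (0.0468 and 0.0138, range 0.0138 to 0.798). The B and plasma cell list passed without chow replicate 5 (0.0207, range 0.0207 to 0.753), and 3 of its members rose without chow replicate 1, 2 or 4. Lcn2, an iron-binding acute phase protein, rose by 3.91 on the log2 scale, or by 5.40 without chow replicate 5.

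All 16 cell cycle genes rose (median 2.26, camera adjusted p = 1.07e-08, and adjusted p = 0.176 with an estimated correlation), with Cdc20, an activator of the anaphase-promoting complex, at 0.788 ± 0.214 and 16.8 ± 7.04 CPM. Bile duct cell markers did not pass as a group (6 of 12 rose and 1 fell, camera adjusted p = 0.197). Their member Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), the matrix phosphoprotein osteopontin, rose 3.82-fold from 50.9 ± 13.3 to 194 ± 120.01 CPM (adjusted p = 0.00061), with libraries that overlapped between the groups. Vascular endothelial markers rose in 4 of 8 cases (camera adjusted p = 0.0751), with Ly6a, which encodes a surface antigen, from 8.9 ± 2.08 to 39.5 ± 9.87 CPM, and sinusoidal endothelial markers rose in 2 of 10 cases (camera adjusted p = 0.853), or in 5 without replicate 3 of the 8-week group.

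Lipid and amino acid metabolism shifted at 8 weeks. Of 18 genes of fatty acid synthesis 12 fell and 1 rose (median -0.88, camera adjusted p = 2.76e-05, and adjusted p = 0.125 with an estimated correlation). Thrsp, an activator of lipogenesis, fell with Scd1, from 195 ± 39.3 to 22.2 ± 11.4 CPM. Of 14 genes of the urea cycle and amino acid breakdown 10 fell and 0 rose (median -0.93, camera adjusted p = 0.000145, and adjusted p = 0.192 with an estimated correlation). The urea cycle enzyme Arg1 went from 1688 ± 406 to 579.9 ± 189 CPM and Tat, which degrades tyrosine, from 2984 ± 997 to 1028 ± 406 CPM. Bile acid synthesis and transport fell in 12 of 19 cases and rose in 3 (median -0.66, camera adjusted p = 0.00109, and adjusted p = 0.378 with an estimated correlation). Cyp7b1 of the alternative synthesis pathway fell from 597 ± 91.2 to 133 ± 60.1 CPM. Cyp7a1, the rate-limiting enzyme of the classic pathway, was at 113 ± 14.8 and 103 ± 30.6 CPM (log2 difference -0.13, adjusted p = 0.762). Genes of choline, phosphatidylcholine and methionine metabolism fell in 7 of 20 cases and rose in 4 (median -0.35, camera adjusted p = 0.0347, and adjusted p = 0.23 with an estimated correlation). Cth of transsulfuration fell from 769 ± 491 to 287 ± 108 CPM and Mat2a, which makes S-adenosylmethionine, rose from 64.4 ± 8.97 to 161 ± 27.6 CPM. The choline list did not pass without chow replicate 1 (0.0662) or 8-week replicate 6 (0.0585, range 0.00576 to 0.348), and 12 members fell without 8-week replicate 3. Pemt, which makes phosphatidylcholine from phosphatidylethanolamine, rose by 0.93 on the log2 scale (adjusted p = 0.0465). That call was lost in 14 of the 21 fits with 1 library left out (chow replicates 1 to 5, 8-week replicates 2, 3 and 4, and 16-week replicates 1, 2, 4, 5, 6 and 7), most without replicate 3 of the 8-week group (0.34, adjusted p = 0.123, with a range of 0.00921 to 0.325 over the alternatives). Lipid droplet genes rose in 5 of 17 cases (camera adjusted p = 0.269), with the fatty acid transporter Cd36 (ENSMUSG00000002944, chromosome 5, 17781690 to 17888801) from 63.6 ± 8.56 to 290.2 ± 99.1 CPM (log2 change 2.19, adjusted p = 1.02e-07). Fatty acid oxidation and PPAR-alpha targets rose in 3 of 18 cases and fell in 4 (median -0.01 but 0.16 with total counts alone, mean 0.24, camera direction down, adjusted p = 0.589). Fgf21, a hormone of the fasted liver, rose within that list from 1.65 ± 0.826 to 90.7 ± 55.3 CPM. Cholesterol synthesis genes rose in 5 of 20 cases and fell in 4 (median 0.17, camera direction down, adjusted p = 0.951). Hepatocyte secreted proteins rose in 4 of 14 cases and fell in 5 (median 0.14, camera direction down, adjusted p = 0.543), and Apob, the core protein of very low density lipoprotein, fell from 7409.5 ± 989 to 2768 ± 674 CPM. In that list 2 fell without chow replicate 3 or 5, or 8-week replicate 2, 4, 6 or 7. Pericentral hepatocyte markers rose in 5 of 12 cases (camera adjusted p = 0.543), with Cyp2e1, a cytochrome of that zone, at 5696 ± 848 and 6112 ± 2730.00 CPM (log2 difference 0.10, adjusted p = 0.84).

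Sex-biased genes were among the largest changes at 8 weeks. Male-biased liver genes fell in 7 of 8 cases (median -2.26, camera adjusted p = 3.66e-05, and adjusted p = 0.192 with an estimated correlation). Moxd1, a monooxygenase-like gene (ENSMUSG00000020000, chromosome 10, 24223517 to 24302790), fell from 72.8 ± 59.3 to 0.206 ± 0.211 CPM (log2 change -8.48, adjusted p = 4.59e-08), and Elovl3, a fatty acid elongase, fell from 1574 ± 262 to 143 ± 88.2 CPM. Mup17 (ENSMUSG00000096688, chromosome 4, 61591929 to 61595871), a major urinary protein, fell by 6.21 on the log2 scale, and reads may be shared between the near-identical genes of its family. Female-biased liver genes rose in 4 of 6 cases and fell in 1 (camera adjusted p = 0.268), with Cyp2b9 (ENSMUSG00000040660, chromosome 7, 26173411 to 26210661) from 0.0372 ± 0.0281 to 50.3 ± 39.6 CPM (adjusted p = 5.56e-09), whose reads can be shared with related Cyp2b genes. Other large falls with no overlap between the groups were in Cyp2b10, a drug-inducible cytochrome (log2 change -6.88), Slc13a2, a citrate transporter (-4.94), and Lrit2 (-4.82). Among the largest rises were Vsig8 and Sprr1a, genes of stratified epithelia. Vsig8 had 1 count on chow and was higher by a pooled ratio of 1850 (95% interval 332 to 73200), and Sprr1a rose by 7.60 on the log2 scale. Without chow replicate 1 the fitted changes were 12.21 for Vsig8, against 10.57 with it, and 8.25 for Sprr1a. Cela2a, a pancreatic elastase (ENSMUSG00000058579, chromosome 4, 141814962 to 141826160), rose by 7.52 (adjusted p = 0.00228), or by 3.62 without replicate 4 of the 8-week group. All 7 measured exocrine pancreas transcripts were called higher, with a camera adjusted p of 0.0751, and 2 were without replicates 3, 4 and 5 of that group (median 3.38). The pancreas list passed without 8-week replicate 1 or 2 (0.0343 and 0.0259, range 0.0259 to 0.753). Red blood cell transcripts (0 rose, 1 fell, 4 not called, median 0.98, mean 0.49, camera direction down, adjusted p = 0.704), fat tissue transcripts (0 of 4 called, median 1.24, camera direction down, adjusted p = 0.784) and mesothelial markers (1 rose, 1 fell, 4 not called, camera adjusted p = 0.539) did not pass as groups.

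In all, edgeR called 8772 of 17104 genes (51.3%) at 8 weeks, 5269 higher and 3503 lower, and 4765 of them changed at least 2-fold, 3505 up and 1260 down. In 5155 genes (30.1%) no library of 1 group overlapped the other, where chance gives 0.155%. Of the 39 lists 19 passed camera, 13 up and 6 down. With an estimated correlation camera called 0, and 9 had an unadjusted p under 0.05. Adjusted over the list alone, the counts of called members were the same, except that 1 more gene was called in activated stellate cells, dendritic cell markers, chemokines, fatty acid synthesis and the circadian clock. With total counts as the sole scaling the median of all genes moved by 0.118 on the log2 scale and 78.3% of the called genes were higher, against 60.1%. The median of all genes was 0.158 in the reported scaling.

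**Figure D2:**
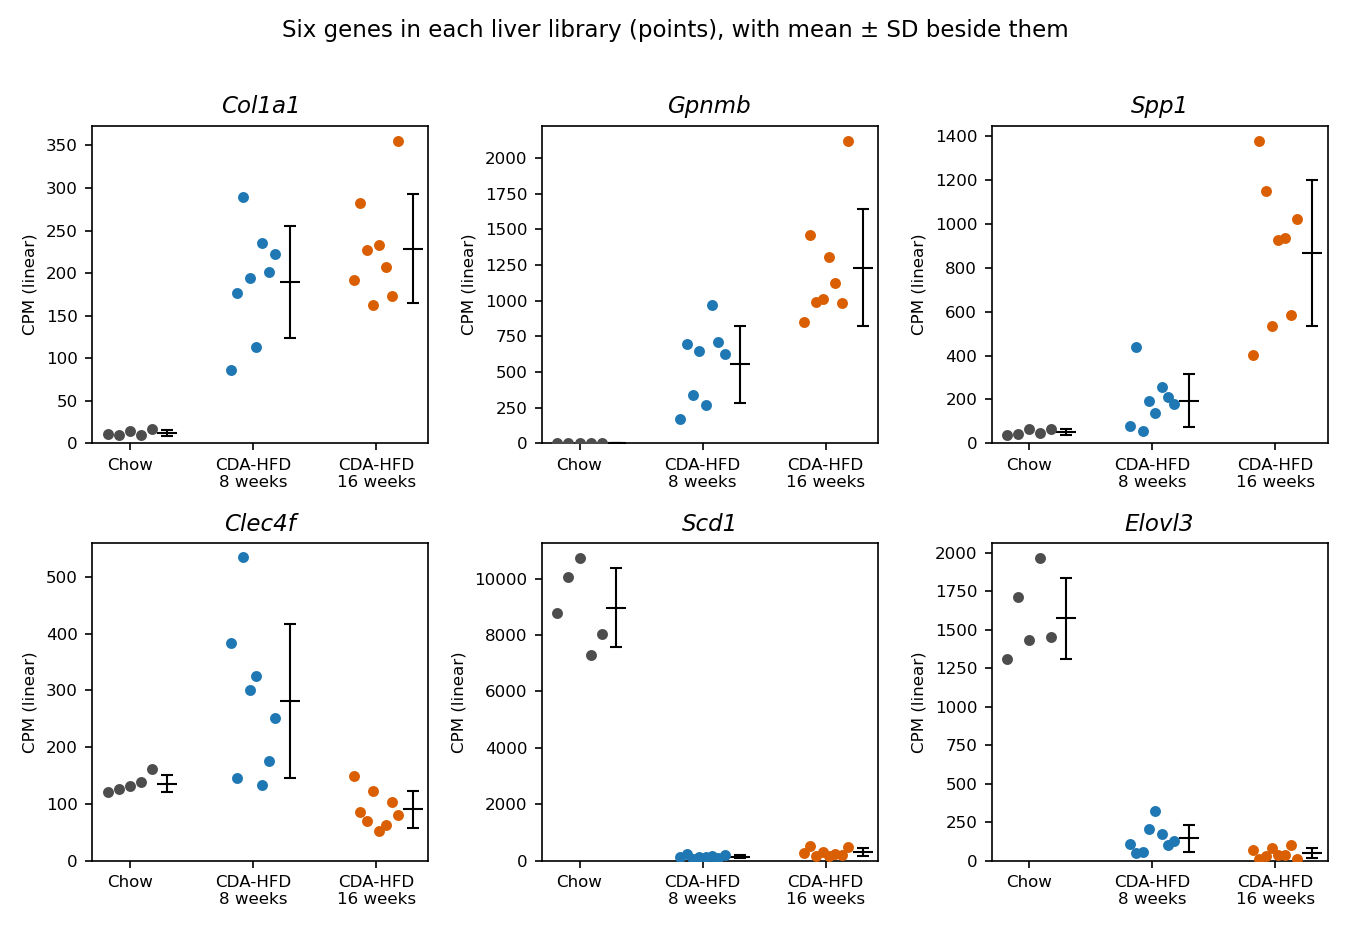
CPM (linear axis) of Col1a1, Gpnmb, Spp1, Clec4f, Scd1 and Elovl3 in the chow, 8-week and 16-week groups, with 1 point per library and the mean ± SD beside them. Spp1 averaged 50.9, 194 and 868 CPM in the 3 groups, and Clec4f averaged 136, 281 and 90.7 CPM.

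The second comparison set 16 weeks of CDA-HFD against the same chow livers, and asks which transcripts differ after a longer time on the diet, with the animals also older. Matrix genes, scar-associated macrophage markers and cell cycle genes were higher at 16 weeks too, and every bile duct cell marker and most B and plasma cell markers were higher. Genes of hepatocyte function were lower across fatty acid synthesis, bile acids, methionine metabolism, the urea cycle and secreted proteins. With an estimated correlation only fatty acid synthesis passed camera at 16 weeks, and 0 lists did without replicate 3 of the 8-week group. Col1a1 stood at 229 ± 63.8 CPM, 18.9-fold above chow (adjusted p = 9.38e-10), and Gpnmb at 1229.8 ± 409 CPM, 3508-fold above chow (adjusted p = 3.06e-11). Spp1 rose 17.0-fold to 868 ± 334 CPM (adjusted p = 2.33e-07), and for these 3 genes every CDA-HFD library lay above every chow library.

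All 15 collagens rose at 16 weeks (median 2.41, camera adjusted p = 4.62e-09, and adjusted p = 0.125 with an estimated correlation), with Col1a2 at 239 ± 55.7 CPM and Col3a1 at 579.7 ± 114 CPM (log2 change 3.45, adjusted p = 2.06e-09). Matrix crosslinking and protease control (15 of 17 rose, 1 fell, median 2.74, camera adjusted p = 3.52e-07, and adjusted p = 0.106 with an estimated correlation) included Lox at 9.74 ± 1.64 CPM (log2 change 3.86, adjusted p = 2.02e-09). Timp1 was at 15.9 ± 5.31 CPM (log2 change 6.25, adjusted p = 3.56e-06). Of 16 matricellular, elastic fibre and proteoglycan genes 15 rose and 1 fell (median 2.39, camera adjusted p = 2.55e-07, and adjusted p = 0.106 with an estimated correlation). Lum, the collagen-binding lumican, rose from 11.9 ± 3.96 to 192 ± 39.5 CPM, and Ltbp2, a protein of elastic microfibrils, from 2.06 ± 0.541 to 35.7 ± 10.9 CPM. Activated stellate cell and myofibroblast markers rose in 10 of 13 cases (median 2.04, camera adjusted p = 8.82e-05, and adjusted p = 0.222 with an estimated correlation). Acta2 was at 23.6 ± 7.92 CPM (log2 change 1.52, adjusted p = 0.018), and its call was lost without replicate 4 of the chow group (1.37, adjusted p = 0.0513, with a range of 0.000166 to 0.0513 over the alternatives). TGF-beta pathway genes rose in 8 of 14 cases and fell in 1 (median 0.73, camera adjusted p = 0.04, and adjusted p = 0.482 with an estimated correlation). Their ligands Tgfb3 and Tgfb2 rose from 2.32 ± 0.709 to 14.8 ± 4.13 CPM and from 1.11 ± 0.141 to 6.06 ± 1.2 CPM. Without replicate 3 of the 8-week group, which shares the fit, the TGF-beta list did not pass (0.067, range 0.0242 to 0.508). Quiescent stellate cell markers went both ways (3 rose, 3 fell, camera adjusted p = 0.959), with 5 higher without that library.

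Each of the 12 bile duct cell markers rose at 16 weeks (median 3.02, camera adjusted p = 1.41e-05, and adjusted p = 0.125 with an estimated correlation). Epcam, an adhesion protein of bile duct and progenitor cells, went from 1.31 ± 0.231 to 29.3 ± 13.6 CPM, with no overlap between the groups. The 13 scar-associated macrophage markers all rose again (median 5.03, camera adjusted p = 1.92e-10, and adjusted p = 0.106 with an estimated correlation), with Trem2 at 92.8 ± 26.9 CPM (log2 change 6.76, adjusted p = 1.07e-06) and Mmp12 at 489.7 ± 106 CPM. Resident Kupffer cell markers were split, with 3 higher and 3 lower of 10 (median 0.00 but -0.04 with DESeq2 size factors, mean -0.65, camera direction down, adjusted p = 0.576). Cd163, a haemoglobin scavenger receptor, fell from 21.7 ± 5.46 to 0.705 ± 0.664 CPM, and Timd4 (ENSMUSG00000055546, chromosome 11, 46810800 to 46844332), a phosphatidylserine receptor of long-lived macrophages, from 10.1 ± 1.11 to 1.24 ± 0.613 CPM. Clec4f was at 90.7 ± 32.6 CPM and not called (log2 difference -0.58, adjusted p = 0.101), but passed without replicate 3 of the 8-week group (adjusted p = 0.0463) or replicate 1 of the 16-week group (0.042), in a range of 0.00108 to 0.8 over the alternatives. Chemokines and cytokines rose in 14 of 17 cases (median 3.37, camera adjusted p = 1.21e-06, and adjusted p = 0.106 with an estimated correlation). Ccl2 stood at 12.9 ± 2.39 CPM (log2 change 3.42, adjusted p = 3.46e-07), Tnf at 4.61 ± 0.627 against 0.192 ± 0.0649 CPM, and Ccl20 was at least 33.8-fold higher. T and NK cell markers rose in 13 of 14 cases and fell in 1 (camera adjusted p = 0.000873, and adjusted p = 0.246 with an estimated correlation). Cd8a rose from 0.322 ± 0.197 to 4.35 ± 2.69 CPM. B and plasma cell markers rose in 9 of 10 cases (median 1.94, camera adjusted p = 0.0173, and adjusted p = 0.482 with an estimated correlation). Jchain, which joins secreted antibodies, rose from 5.25 ± 4.996 to 43.5 ± 31.8 CPM. Without replicate 5 of the chow group, the log2 change of Jchain was 3.68, against 3.05 with it. Dendritic cell markers (7 of 8 rose, camera adjusted p = 0.000997, and adjusted p = 0.106 with an estimated correlation), neutrophil markers (6 of 9 rose, camera adjusted p = 0.00286, and adjusted p = 0.299 with an estimated correlation) and interferon-stimulated genes (12 of 13 rose, camera adjusted p = 8.82e-05, and adjusted p = 0.106 with an estimated correlation) also passed. Flt3, a receptor of dendritic cell development, rose by 2.93 and Oasl2, an antiviral gene, by 2.51 on the log2 scale. Mpo, a granule enzyme of neutrophils, rose from 0.0302 ± 0.0309 to 0.533 ± 0.397 CPM.

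The 16 cell cycle genes all rose at 16 weeks (median 2.90, camera adjusted p = 8.13e-09, and adjusted p = 0.109 with an estimated correlation), with Ccnb1, the mitotic cyclin, at 0.0956 ± 0.0809 and 1.64 ± 0.833 CPM. Of the endothelial lists, vascular markers rose in 3 of 8 cases (camera adjusted p = 0.173), with Cd34 from 4.45 ± 2.03 to 33.1 ± 6.07 CPM. Sinusoidal markers rose in 1 and fell in 3 of 10 cases (median -0.24 but 0.28 with total counts alone, camera adjusted p = 0.296). Oit3, a gene of sinusoidal endothelium, fell within that list from 47.0 ± 3.3 to 29.1 ± 7.17 CPM. Mesothelial markers rose in 2 of 6 cases (camera adjusted p = 0.394), with Wt1, a transcription factor of mesothelium, from 0.594 ± 0.256 to 3.91 ± 1.14 CPM.

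Fatty acid synthesis fell in 15 of 18 cases at 16 weeks (median -1.35, camera adjusted p = 9.31e-07, and adjusted p = 0.0458 with an estimated correlation). With an estimated correlation the list did not pass without replicate 3 of the 8-week group (adjusted p = 0.278, range 1.11e-09 to 0.278 over the alternatives). Scd1 was at 291 ± 147 CPM (log2 change -4.95, adjusted p = 1e-09) and Thrsp at 9.72 ± 6.38 CPM. Urea cycle and amino acid breakdown genes fell in 13 of 14 cases (median -1.43, camera adjusted p = 1.71e-06, and adjusted p = 0.106 with an estimated correlation). Hal, which degrades histidine, fell from 609 ± 157 to 159 ± 55.9 CPM. Bile acid genes fell in 14 of 19 cases and rose in 2 (median -1.24, camera adjusted p = 4.09e-06, and adjusted p = 0.175 with an estimated correlation). Cyp7b1 was at 70.1 ± 41.2 CPM, and Cyp7a1 fell to 48.2 ± 25.2 CPM (log2 change -1.23, adjusted p = 0.00304), with -0.72 and an adjusted p of 0.0657 under total counts alone, the highest of its alternatives (range 9.1e-05 to 0.0657). Choline, phosphatidylcholine and methionine genes fell in 12 of 20 cases and rose in 1 (median -0.76, camera adjusted p = 0.000679, and adjusted p = 0.106 with an estimated correlation). Ahcy, which clears S-adenosylhomocysteine, fell from 146 ± 31.7 to 43.5 ± 8.86 CPM. Pemt was at 283 ± 56.8 CPM (log2 difference -0.15, adjusted p = 0.764). Hepatocyte secreted proteins fell in 8 of 14 cases (median -0.77, camera adjusted p = 0.000873, and adjusted p = 0.246 with an estimated correlation). Fga, a fibrinogen chain, fell from 8718 ± 2528 to 3348 ± 737 CPM. Cholesterol synthesis genes fell in 8 of 20 cases (median -0.28 but 0.24 with total counts alone, camera adjusted p = 0.0215, and adjusted p = 0.585 with an estimated correlation), and did not pass without replicate 2 of the 16-week group (0.0659, range 0.00468 to 0.669). Insig1, a sterol-responsive regulator, fell from 261 ± 27.0 to 113 ± 28.4 CPM. Cd36 rose to 425 ± 44.7 CPM (log2 change 2.74, adjusted p = 4.24e-09), while lipid droplet genes as a group did not pass (6 rose, 3 fell, 8 not called, camera adjusted p = 0.959). Fatty acid oxidation genes (2 rose, 7 fell of 18, median -0.26 but 0.27 with total counts alone, camera adjusted p = 0.115) did not pass, although Fgf21 rose to 68.5 ± 40.8 CPM. Acute phase proteins (1 rose, 7 fell of 14, median -0.48 but 0.03 with total counts alone, camera adjusted p = 0.283) and pericentral markers (4 rose, 2 without replicate 1 of the chow group, and 1 fell of 12, camera adjusted p = 0.913) did not pass either. The median log2 CPM over the acute phase list was 9.46 and 9.74 in chow replicates 3 and 5. In chow replicates 1, 2 and 4 it was 7.02, 7.15 and 7.48. All 16-week livers lay between these, at 8.23 to 8.53, so the direction depends on which chow livers are compared. Cyp2e1 was at 4542 ± 1853 CPM (log2 difference -0.33, adjusted p = 0.509).

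Male-biased liver genes fell in 8 of 8 cases at 16 weeks (median -3.73, camera adjusted p = 2.17e-06, and adjusted p = 0.106 with an estimated correlation). Elovl3 was at 46.4 ± 32.1 CPM and Moxd1 at 0.104 ± 0.0939 CPM (log2 change -9.38). The largest falls with no overlap between the groups also took in Mup17 (log2 change -9.79), Mup7 (-7.09), Mup16 (-6.92) and Mup11 (-6.89), and Cyp2b10 (-6.84). Mup7 fell by 7.79 without replicate 7 of the 16-week group. Female-biased genes rose in 3 of 6 cases and fell in 1 (camera adjusted p = 0.356), with Cyp2b9 at 15.8 ± 6.17 CPM (log2 change 8.63). The largest rises, beside Gpnmb, Mmp12 and Vsig8, were in Krt13, Vmn2r3 and Ighv10-3. Krt13 (ENSMUSG00000044041, chromosome 11, 100117327 to 100121566), a keratin of squamous epithelium, had no count on chow and was at least 1500-fold higher (adjusted p = 0.0151), with a fitted log2 change of 12.35 without replicate 1 of the 16-week group against 13.18. Krt13 was at 111, 32.1 and 66.1 CPM in 16-week replicates 1, 4 and 7, which were high in squamous transcripts. The other 16-week libraries held 0.749 to 4.31 CPM of it. Vsig8 was higher by a pooled ratio of 1120 (95% interval 201 to 44300) and Vmn2r3, a vomeronasal receptor, by 1150 (95% interval 206 to 45300). Fitted log2 changes were 11.24 for Vsig8 without replicate 1 of the chow group, against 9.59, and 11.17 for Vmn2r3 without replicate 5 of that group, against 9.55. Ighv10-3, an antibody segment with close relatives, was higher by a pooled ratio of 633 (95% interval 175 to 5230), and by a fitted log2 change of 6.75 without replicate 4 of the 16-week group, against 9.001. Exocrine pancreas transcripts (0 of 7 called, median 0.28, camera direction down, adjusted p = 0.738), red blood cell transcripts (0 rose, 2 fell of 5, or 1 without chow replicate 1 or 3 or 16-week replicate 1, 4, 5, 7 or 8, camera adjusted p = 0.108) and fat tissue transcripts (0 of 4 called, camera adjusted p = 0.597) did not pass as groups.

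In all, edgeR called 8873 of 17104 genes (51.9%) at 16 weeks, 5026 higher and 3847 lower, and 5170 changed at least 2-fold, 3791 up and 1379 down. Libraries did not overlap between the groups in 8633 genes (50.5%), where chance gives 0.155%. Of the lists 22 passed camera, 15 up and 7 down, and 1, fatty acid synthesis, did with an estimated correlation (0 without replicate 3 of the 8-week group), where 13 had an unadjusted p under 0.05. Adjusted over the list alone, 16 crosslinking genes rose and 14 urea cycle genes fell, 5 quiescent stellate cell markers rose, 0 rose and 2 fell among sinusoidal markers, 4 rose and 2 fell among female-biased genes, 1 fell among red blood cell transcripts, and the other lists kept their counts. Total counts as the sole scaling moved the median of all genes by 0.528 and gave 89.5% higher among called genes, against 56.6%. Of the genes called at 8 weeks, 6687 were called at 16 weeks with the same sign, 3885 higher and 2802 lower, and 9 with the opposite sign. That is 76.2% of the calls at 8 weeks, where independent calls would share 2336.2. Both comparisons use the same chow livers. With the chow livers split so that each comparison had its own, 3736 to 4572 genes were shared in 20 fits, against 1004.3 to 1278.7 for independent calls.

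**Figure D3:**
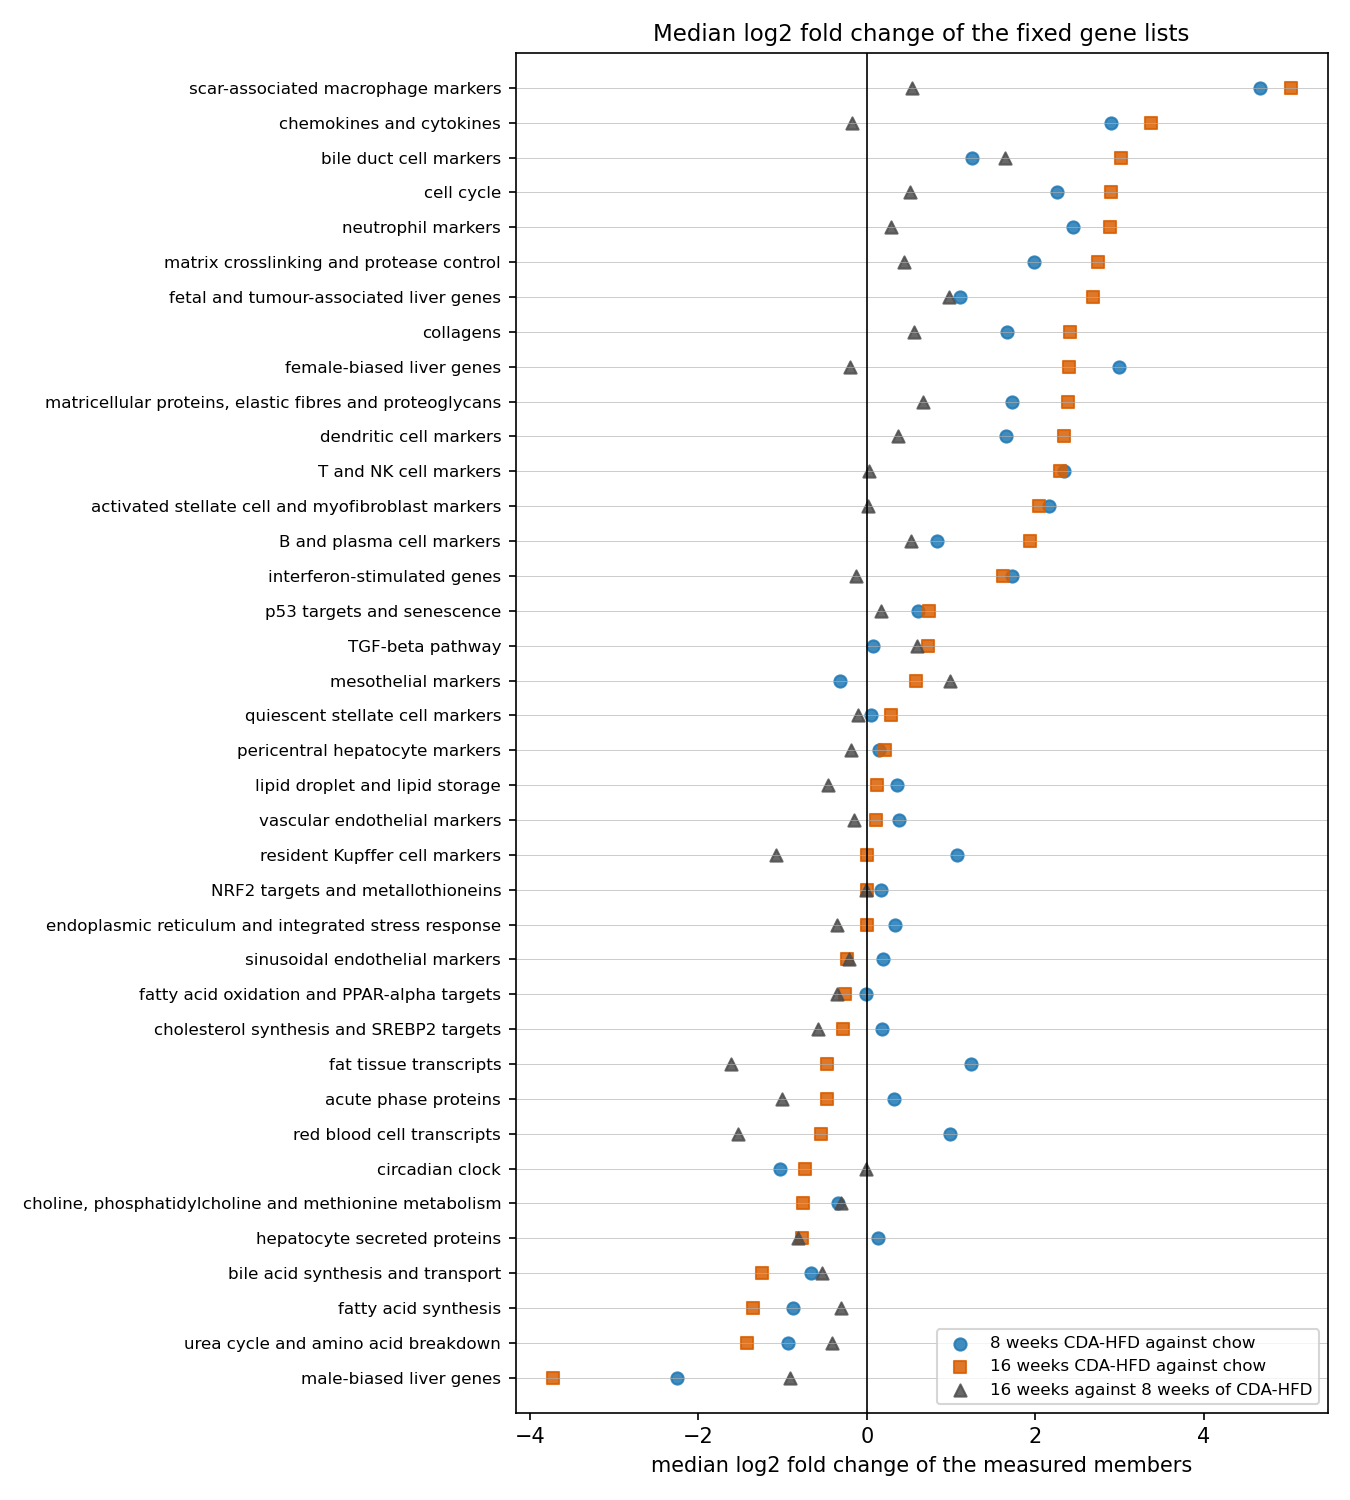
Median log2 change of the measured members of 38 gene lists in the 3 comparisons, with the exocrine pancreas list left out. Scar-associated macrophage markers had medians of 4.67 and 5.03 against chow, and male-biased liver genes -2.26 and -3.73.

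The third comparison set 16 weeks against 8 weeks of CDA-HFD, and asks what differed with more time on the diet, again not separable from age. Bile duct cell markers, collagens and proteoglycans were higher at 16 weeks, while resident Kupffer cell markers and hepatocyte secreted proteins were lower. As groups they passed camera with the preset correlation, and 0 lists passed with an estimated one. Spp1 rose 4.47-fold from 194 ± 120.01 to 868 ± 334 CPM (adjusted p = 0.000257), and Epcam from 4.19 ± 3.68 to 29.3 ± 13.6 CPM (log2 change 2.80, adjusted p = 5.51e-05). Timd4 fell from 13.2 ± 8.19 to 1.24 ± 0.613 CPM (log2 change -3.40, adjusted p = 1.34e-05) and Marco from 139 ± 70.8 to 18.1 ± 9.57 CPM (log2 change -2.94, adjusted p = 2.64e-05), with no overlap of libraries for both. Clec4f fell from 281 ± 136 to 90.7 ± 32.6 CPM (log2 change -1.63, adjusted p = 0.000304), with some overlap.

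Bile duct cell markers rose in 10 of 12 cases between 8 and 16 weeks, and in 12 adjusted over the list alone (median 1.64, camera adjusted p = 8.2e-11, and adjusted p = 0.133 with an estimated correlation). Cftr, a chloride channel of the ducts, went from 0.412 ± 0.235 to 3.62 ± 1.53 CPM. Collagens rose in 9 of 15 cases, and in 11 adjusted over the list alone (median 0.56, camera adjusted p = 8.49e-06, and adjusted p = 0.264 with an estimated correlation). Col6a3 rose from 51.5 ± 17.6 to 121 ± 33.4 CPM. Col1a1 was not called (log2 difference 0.27, adjusted p = 0.383), but passed without the 5 libraries highest in squamous transcripts (0.66, adjusted p = 0.0345) and with total counts alone (0.70, 0.0346), in a range of 0.0345 to 0.671 over the alternatives. Col3a1 was at the limit (0.56, adjusted p = 0.049). The call of Col3a1 was lost in 16 of the 21 fits with 1 library left out (chow replicates 1 to 5, 8-week replicates 1 to 5, and 16-week replicates 1, 2, 3, 5, 6 and 8, adjusted p up to 0.103, in a range of 0.00956 to 0.207 over the alternatives). Matricellular, elastic fibre and proteoglycan genes rose in 9 of 16 cases, and in 10 adjusted over the list alone (median 0.66, camera adjusted p = 6.9e-06, and adjusted p = 0.264 with an estimated correlation). Eln, which encodes elastin, rose from 22.5 ± 6.67 to 52.8 ± 14.99 CPM and Lum from 80.7 ± 31.2 to 192 ± 39.5 CPM. Crosslinking and protease control genes rose in 7 of 17 cases, and in 9 adjusted over the list alone (median 0.45, camera adjusted p = 0.00594, and adjusted p = 0.33 with an estimated correlation). Lox rose by 0.75 on the log2 scale (adjusted p = 0.0168, but 0.54 and 0.0964 without replicates 3, 4 and 5 of the 8-week group, range 0.00353 to 0.0964), Mmp2, a gelatinase, from 29.1 ± 12.7 to 74.0 ± 22.1 CPM, and Timp1 was not called (-0.93, adjusted p = 0.196), nor without replicate 3 of the 8-week group (0.09). TGF-beta pathway genes rose in 7 of 14 cases (median 0.59, camera adjusted p = 6.33e-05, and adjusted p = 0.264 with an estimated correlation). Tgfb3 rose from 4.68 ± 1.41 to 14.8 ± 4.13 CPM. Activated stellate cell markers rose in 3 of 13 cases (median 0.02 but -0.01 with DESeq2 size factors, mean -0.09, camera direction up, adjusted p = 0.12), and passed without replicate 3 of the 8-week group (0.00772, range 0.00292 to 0.67). Those that rose include them Pdgfra, a receptor of fibroblasts, from 17.4 ± 8.91 to 54.1 ± 14.2 CPM, while Acta2 was not called (-0.97, adjusted p = 0.103), nor without that library (-0.19). Quiescent stellate cell markers went both ways (2 rose, 2 fell of 11, median -0.10 but 0.32 with total counts alone, camera adjusted p = 0.6). Mesothelial markers rose in 4 of 6 cases, and in 5 adjusted over the list alone (median 0.99, camera adjusted p = 0.00198, and adjusted p = 0.264 with an estimated correlation). Wt1 rose from 1.47 ± 0.718 to 3.91 ± 1.14 CPM. Without replicate 4 of the 8-week group, or replicate 1, 6 or 7 of the 16-week group, 2 mesothelial markers rose.

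Resident Kupffer cell markers fell in 9 of 10 cases (median -1.07, camera adjusted p = 3.3e-08, and adjusted p = 0.139 with an estimated correlation). Cd163 fell from 13.03 ± 10.8 to 0.705 ± 0.664 CPM. Scar-associated macrophage markers rose in 5 of 13 cases, and in 6 adjusted over the list alone (median 0.54, camera adjusted p = 0.00159, and adjusted p = 0.393 with an estimated correlation). Gpnmb rose 2.22-fold to 1229.8 ± 409 CPM (adjusted p = 0.0122), and Trem2 was not called (-0.34, adjusted p = 0.676), nor without replicate 3 of the 8-week group (0.73). Of the scar-associated markers 9 rose without replicate 3 and 3 without replicate 5 of the 8-week group, and 3, 2, 2 and 1 without replicates 2, 5, 6 and 8 of the 16-week group. Dendritic cell markers rose in 2 of 8 cases, and in 3 adjusted over the list alone (camera adjusted p = 0.0475, and adjusted p = 0.264 with an estimated correlation). Itgae, an integrin chain, rose from 1.05 ± 0.375 to 2.15 ± 0.605 CPM. The dendritic list did not pass without chow replicate 5, 8-week replicate 1, 5 or 8, or 16-week replicate 3, 5, 6 or 7 (adjusted p 0.0509 to 0.0825, in a range of 0.0294 to 0.355), and 1 member rose without replicate 5 of the 16-week group. T and NK cell markers (1 rose, 1 fell of 14, median 0.02, mean -0.14, camera adjusted p = 0.944), neutrophil markers (1 of 9 rose, 0 adjusted over the list alone, camera adjusted p = 0.469) and B and plasma cell markers (4 of 10 rose, camera adjusted p = 0.0944) did not pass. The B and plasma cell list did without replicate 3 or 4 of the 8-week group (0.0415 and 0.0384) or replicate 2 or 5 of the 16-week group (0.0139 and 0.0414, range 0.00446 to 0.669). Gzma, a granzyme of T and NK cells, fell from 3.11 ± 2.05 to 0.973 ± 0.185 CPM. Chemokines and cytokines did not pass as a group (2 rose, 2 fell of 17, median -0.18 but 0.14 with total counts alone, camera adjusted p = 0.799), and Ccl2 was not called (-0.18, adjusted p = 0.69). Cx3cl1, a membrane-bound chemokine, rose from 8.22 ± 3.41 to 24.9 ± 7.17 CPM, and Ccl24, which attracts eosinophils, fell from 9.96 ± 6.77 to 2.51 ± 0.659 CPM. Interferon-stimulated genes rose in 1 of 13 cases (median -0.13 but 0.28 with total counts alone, camera adjusted p = 0.944). Cell cycle genes rose in 5 of 16 cases, and in 6 adjusted over the list alone (median 0.51, camera adjusted p = 0.0035, and adjusted p = 0.402 with an estimated correlation). In that list 3 rose without replicate 5 of the 8-week group or replicate 2, 5 or 6 of the 16-week group, and 1 without replicate 8 of the latter.

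Hepatocyte secreted proteins fell in 12 of 14 cases, and in 13 adjusted over the list alone (median -0.82, camera adjusted p = 3.88e-08, and adjusted p = 0.141 with an estimated correlation), and 7 fell with total counts alone. Apoa1, the main protein of high density lipoprotein, fell by 1.73 on the log2 scale, or by 0.75 without replicate 3 of the 8-week group. Acute phase proteins fell in 10 of 14 cases, and in 12 adjusted over the list alone (median -1.01, camera adjusted p = 6.62e-07, and adjusted p = 0.264 with an estimated correlation). Cholesterol synthesis genes fell in 10 of 20 cases, and in 13 adjusted over the list alone (median -0.58, camera adjusted p = 5.19e-06, and adjusted p = 0.264 with an estimated correlation). They fell in 17 cases without replicate 3 and in 6 without replicate 5 of the 8-week group, in 6, 6 and 4 without replicates 5, 6 and 8 of the 16-week group, and in 2 with total counts alone. Bile acid genes fell in 10 of 19 cases, and in 11 adjusted over the list alone (median -0.54, camera adjusted p = 1.08e-05, and adjusted p = 0.264 with an estimated correlation). Cyp7a1 fell from 103 ± 30.6 to 48.2 ± 25.2 CPM (adjusted p = 0.0123) and Cyp8b1, which makes cholic acid, from 734 ± 249 to 354 ± 162 CPM. The call of Cyp7a1 was lost without replicates 3, 4 and 5 of the 8-week group (-0.98, adjusted p = 0.0508) and with total counts alone (-0.72, 0.0671, range 0.00084 to 0.0671). Without replicate 8 of the 16-week group 6 bile acid, 5 choline and 4 cholesterol genes fell, and 6 choline genes did without replicate 5 or 6 of that group. Choline and methionine genes fell in 10 of 20 cases, with 1 more rise adjusted over the list alone (median -0.31 but 0.08 with total counts alone, camera adjusted p = 0.00112, and adjusted p = 0.141 with an estimated correlation). Pemt fell by 1.08 (adjusted p = 0.0251), or by 0.49 without replicate 3 of the 8-week group (0.0289), and its call was lost without replicate 8 of the 16-week group (adjusted p = 0.0552), in a range of 0.0078 to 0.145 over the alternatives. Urea cycle and amino acid genes fell in 5 of 14 cases, and in 7 adjusted over the list alone (median -0.41, camera adjusted p = 0.00079, and adjusted p = 0.264 with an estimated correlation), and in 3 without replicate 5 of the 8-week group or replicate 5 or 6 of the 16-week group. Fatty acid synthesis genes fell in 5 of 18 cases and rose in 1, and 6 fell adjusted over the list alone (median -0.31 but 0.07 with total counts alone, camera adjusted p = 0.00231, and adjusted p = 0.211 with an estimated correlation), and 3 fell without replicate 2, 3, 5 or 8 of the 16-week group. The gene that rose was Scd1, 2.04-fold from 143 ± 58.9 to 291 ± 147 CPM (adjusted p = 0.0186, but 0.81 on the log2 scale and 0.0854 without replicates 3, 4 and 5 of the 8-week group, range 0.00284 to 0.0854). Fatty acid oxidation genes fell in 6 of 18 cases (median -0.35 but 0.02 with total counts alone, camera adjusted p = 0.00687, and adjusted p = 0.264 with an estimated correlation). Acadvl, a mitochondrial dehydrogenase, fell from 573 ± 243 to 373 ± 39.4 CPM. Cd36 rose by 0.55 (adjusted p = 0.0307), which was lost without replicate 1 or 5 of the 8-week group or replicate 2, 5 or 8 of the 16-week group (adjusted p 0.051 to 0.0646, in a range of 0.00838 to 0.107 over the alternatives). Lipid droplet genes (2 rose, 5 fell of 17, and 8 fell adjusted over the list alone, median -0.47 but 0.08 with total counts alone, camera adjusted p = 0.0876) and pericentral markers (1 of 12 rose, 0 adjusted over the list alone, median -0.19 but 0.16 with total counts alone, camera adjusted p = 0.284) did not pass. The lipid droplet list did without replicate 8 of the 8-week group (0.0487) or replicate 2 of the 16-week group (0.0477, range 0.0216 to 0.638). Cyp2e1 was not called (-0.43, adjusted p = 0.386), but passed without the 5 libraries highest in squamous transcripts (-0.93, adjusted p = 0.0216, the lowest of a range up to 0.831 over the alternatives).

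Male-biased liver genes fell in 5 of 8 cases (median -0.92, camera adjusted p = 0.00104, and adjusted p = 0.264 with an estimated correlation). Serpina1e, a protease inhibitor with close relatives, fell from 3245 ± 1739 to 829 ± 708 CPM and Mup16 from 9.93 ± 8.05 to 1.33 ± 1.08 CPM (log2 change -2.89, adjusted p = 0.00279). Female-biased genes fell in 2 of 6 cases (median -0.21 but 0.31 with total counts alone, camera adjusted p = 0.587), Cyp2b9 among them (-1.67, adjusted p = 0.00525). Sinusoidal endothelial markers fell in 3 of 10 cases, and in 4 adjusted over the list alone (median -0.21 but 0.14 with total counts alone, camera adjusted p = 0.0139, and adjusted p = 0.33 with an estimated correlation). Dnase1l3, a secreted nuclease, fell from 103 ± 19.4 to 59.2 ± 16.2 CPM, and 5 sinusoidal markers fell without replicate 3 of the 8-week group. Vascular markers went both ways (1 rose, 2 fell of 8, median -0.15, mean 0.03, 0.23 in the median with total counts alone, camera adjusted p = 0.787), with Cd34 from 14.3 ± 4.57 to 33.1 ± 6.07 CPM. The largest rises with no overlap between the groups were in Scube3, which enhances TGF-beta signalling (ENSMUSG00000038677, chromosome 17, 28142141 to 28174854, from 1.17 ± 0.813 to 11.5 ± 4.16 CPM, adjusted p = 4.59e-06), in Fbn2, a fibrillin (log2 change 3.09), and in Scara3, a scavenger receptor-like gene (2.98). Next came Ehf, an epithelial transcription factor (2.94), ccdc198 (2.84) and Mal, a membrane protein of polarized epithelia (2.84). Beside Timd4, Marco, Mup16 and Ccl24, the largest falls were in Cela2a (-7.42, but -3.52 without replicate 4 of the 8-week group) and Dnaic1, a dynein of cilia (-2.06). All 7 exocrine pancreas transcripts fell (median -10.63, camera adjusted p = 0.000114, and adjusted p = 0.264 with an estimated correlation), and 2 did without replicates 3, 4 and 5 of the 8-week group (median -3.20). Red blood cell transcripts fell in 4 of 5 cases, in 2 without replicate 5 of the 16-week group, and in 1 without replicate 3 of the 8-week group or replicate 8 of the 16-week group (median -1.53, camera adjusted p = 0.00808, and adjusted p = 0.33 with an estimated correlation). Fat tissue transcripts were not called (0 of 4, camera adjusted p = 0.6).

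In all, edgeR called 3703 of 17104 genes (21.6%) between 8 and 16 weeks, 1814 higher and 1889 lower, and 1455 changed at least 2-fold, 902 up and 553 down. In 528 genes (3.09%) the libraries did not overlap, where chance gives 0.0155%. The count was 2248 without replicate 8 and 2455 without replicate 5 of the 16-week group, and the 2-fold count was 914 without replicates 3, 4 and 5 of the 8-week group. The balance of directions depended on single libraries. Without replicate 3 of the 8-week group 1034 genes were 2-fold up and 138 down. Without replicates 2, 5, 6 and 8 of the 16-week group 1220, 1004, 1137 and 904 were lower, and 346, 279, 340 and 246 were 2-fold down, while 2835 were lower without replicate 6 of the 8-week group. Of the lists 24 passed camera, 10 up and 14 down. With an estimated correlation camera called 0, and 6 had an unadjusted p under 0.05. Lists not given with a count adjusted over the list alone kept their counts, and counts of 1 or 2 called members mostly moved between 0 and 4 with 1 library left out. Total counts as the sole scaling moved the median of all genes by 0.376, and gave 94.8% higher among called genes, against 49%.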

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

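The tests on squamous epithelium transcripts, on male-biased genes and on the slope with transcript length were chosen after the results were seen.

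Of 165 checks for a library far from the rest of its group, 21 gave one by Dixon's criterion, where chance gives about 1 in 20, or 8.25. Replicate 3 of the 8-week group was the library in 11 of the 21. Values are the gap to the nearest library as a share of the range of the group. On chow, replicate 1 stood apart for Vsig8 (1, high), Mup17 (0.787, low) and Mup7 (0.725, low), replicate 5 for Vmn2r3 (1, high) and replicate 2 for Ccl24 (0.836, low). In the 8-week group, replicate 3 stood apart for Acta2 (0.585) and Pemt (0.567) on the high side, and for Ccl2 (0.553), Cyp2e1 (0.707) and Fbn2 (0.556) on the low side. It also stood apart for the TMM factor (0.578, low), the share of the 10 most abundant genes (0.634, high), the mitochondrial share (0.674, low), the haemoglobin share (0.673, high) and fat tissue transcripts (0.551, high). Other 8-week libraries stood apart for Cyp7a1 (0.635, replicate 2, low), Cyp2b10 (0.541, replicate 7, low) and Ighv10-3 (0.546, replicate 1, high). In the 16-week group these were Cela2a (0.654, replicate 2, low) and the total count (0.544, replicate 3, low at 35254088).

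Levels differed between 16 and 8 weeks of the diet, by the edgeR test of 16 against 8 weeks, in 28 of the 42 genes screened. Of these, 15 were higher and 13 lower at 16 weeks, with the animals also older. The screen took the panel genes and the genes with the largest changes, and left out the examples from the lists. The 6 largest rises and 6 largest falls at 16 against 8 weeks entered because that same test called them. The count of 28 is therefore raised by the choice of genes. Over all genes tested, 21.6% were called at 16 against 8 weeks. The log2 effect at 16 weeks minus that at 8 weeks was 0.558 for Col3a1, 0.75 for Lox, 2.16 for Spp1, 1.15 for Gpnmb, 0.55 for Cd36, 1.03 for Scd1 and 0.748 for Mmp12. It was 3.29 for Scube3, 3.09 for Fbn2, 2.98 for Scara3, 2.94 for Ehf, 2.84 for ccdc198 and 2.84 for Mal, and 1.74 for Vmn2r3 and 6.4 for Ighv10-3. On the lower side it was -1.63 for Clec4f, -3.4 for Timd4, -2.94 for Marco and -1.98 for Ccl24, and -1.1 for Cyp7a1, -1.08 for Pemt, -1.67 for Cyp2b9 and -2.06 for Dnaic1. It was -3.58 for Mup17, -3.17 for Mup7, -2.89 for Mup16 and -3.47 for Mup11, and -7.42 for Cela2a.

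Replicate 3 of the 8-week group differed at least 2-fold from the other libraries of its group in 9879 genes, where the other CDA-HFD libraries did so in 350 to 1887. RNA of another tissue mixed into liver RNA lowers liver transcripts by about its own share, and 54.1% of those genes were lower. That share of lower genes cannot decide on a mixture, since it was taken after TMM scaling and the amount of added RNA was not measured. The TMM factor was 0.4955 in this library and 0.8836 to 1.167 in the others of its group. Loss of RNA by transcript length is left open, since the correlation of its difference with transcript length across genes (rho -0.404) lay within the range of the other libraries (-0.563 to 0.579), while the slope (-2.65 per 10-fold length) lay outside theirs (-1.13 to 0.738). Genes are not independent replicates, and no biological explanation was tested because the labels set this library in no group of its own.

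Squamous epithelium transcripts were not a uniform response of the liver to the diet, since the highest library of the 16-week group held 157 times the lowest. Carry-over between samples and tissue taken with the liver stay open. The labels give running numbers but do not say that these follow the order of processing, and they hold no record of dissection. Along those numbers squamous transcripts fell after peaks, as 1901, 19.02 and 3.153 CPM in 8-week replicates 3 to 5. They did so again from 8-week replicate 6 (316.9, 14.96, 3.437) and 16-week replicates 1 (279.4, 11.28, 6.386) and 4 (82.61, 5.037, 1.78). Pancreas transcripts fell from 7907 and 347.9 to 43.48, 16.61 and 10.29 CPM in 8-week replicates 4 to 8. Carry-over could give such falls, but was not tested. None of the 10 genes reached 1 CPM in a chow liver.

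Male-biased liver genes fell on CDA-HFD, and 3 technical explanations are argued against. Female animals are, since 0 CDA-HFD libraries had Xist at 1 CPM or more. Reads shared between near-identical genes are, since 5 of 5 list members outside the Mup, Cyp4a12 and Serpina1 families were called lower at both times. A loss of hepatocyte transcripts as large as this fall is at 8 weeks. Hepatocyte secreted proteins had a median log2 change of 0.137 (SD over members 0.865) and male-biased genes -2.26. The 0.137 includes replicate 3, with a median log2 CPM of 13.43. The other 8-week livers had 11.65 to 12.68 and chow 12.51 to 12.93, so a smaller loss stays open. A response of sex-biased expression to the diet is an untested hypothesis found on these data.

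Exchanging group labels in 100 splits per comparison cannot show less than 1 in 100, nor tell diet from other differences between the groups. At 8 weeks against chow only the labelled split reached the 8772 genes called (highest other split 5454) and the 4765 changed 2-fold (3086). For the 19 lists chance is not excluded (24, 17 splits as large). The same holds at 16 weeks against chow, with 8873 genes (1550), 5170 changed 2-fold (1024) and 22 lists (29, 34 splits). At 16 against 8 weeks it holds with 3703 genes (482), 1455 changed 2-fold (329) and 24 lists (28, 5 splits).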

How the results depend on the processing

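The alternatives without 8-week replicates 3, 4 and 5, without the 5 libraries highest in squamous transcripts, with total counts alone, and with a correlation estimated without 8-week replicate 3 were chosen after the values were seen. Of 280 pairs of a named gene and a comparison, 217 kept call and direction under all alternatives and 0 changed direction where either value was called. Values not called did change sign, those of Trem2 and Timp1 at 16 against 8 weeks among them. Over all alternatives named genes kept both in 8065 cases, lost the call in 284 and gained it in 11. With an estimated inter-gene correlation 0, 1 and 0 lists passed camera in the 3 comparisons, in place of 19, 22 and 24, and 0, 0 and 0 without replicate 3 of the 8-week group. Genes called at 16 against 8 weeks, 3703 as reported, were 2226 in a fit of only these 2 groups and 5579 without the 5 libraries highest in squamous transcripts. The 1455 changed at least 2-fold became 914 without 8-week replicates 3, 4 and 5. Genes shared by both comparisons with chow, 6687 as reported, were 3643 with a limit of 2-fold, which counts fewer genes by construction. For the other changes the cause was not tested.

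Leaving out each library in turn gave 7563 to 9748 genes, 3915 to 5117 with 2-fold change and 17 to 21 lists at 8 weeks against chow. The ranges were 8099 to 11308, 4960 to 5310 and 21 to 22 at 16 weeks against chow, and 2248 to 5132, 993 to 1900 and 23 to 26 at 16 against 8 weeks. With total counts as the sole scaling, the medians of 5 lists that had passed camera changed sign, as did others that had not passed. Cholesterol synthesis at 16 weeks against chow was 0.2356 in place of -0.28, and at 16 against 8 weeks sinusoidal endothelial markers were 0.1361, fatty acid synthesis 0.07478, fatty acid oxidation 0.0202 and choline and methionine genes 0.08458. Under this scaling another 42 list medians moved by more than 1 SD and 70 did not, while with DESeq2 size factors and with the 20 most abundant genes left out 0 of 117 did. Apart from fits of 2 groups and left-out libraries, alternatives fixed in advance kept totals called and 2-fold within 1.5 times the reported ones. Counts by direction moved further. At 16 against 8 weeks 1082 genes were lower with no filter (1889 as reported), 472 were 2-fold higher at a mean of 1 CPM (902) and 362 were 2-fold lower by the DESeq2 Wald test (553). At 16 weeks against chow 2525 were 2-fold higher at a mean of 1 CPM (3791). In fits of 2 groups 3356 were higher at 8 weeks (5269) and 5850 lower at 16 weeks (3847) against chow. At 16 against 8 weeks 781 were lower (1889), 228 of them 2-fold (553). Depth limits genes at or under the floor of 0.0184 CPM on chow, where folds are bounds or ratios with wide intervals. No paired analysis was possible because the labels give each library its own running number.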

Other observations

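The relations between list scores were planned, while scaling by total counts alone was chosen after the values were seen.

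In 3 stress and growth lists genes differed with the diet one by one, while none of the 3 passed camera against chow. Among 13 NRF2 targets and metallothioneins, 6 rose and 3 fell at 8 weeks (camera adjusted p = 0.234) and 6 rose and 2 fell at 16 weeks (median -0.00 but mean 1.10, 0.54 in the median with total counts alone, camera adjusted p = 0.156). Slc7a11, the cystine importer, rose from 0.0629 ± 0.0626 to 5.71 ± 2.88 CPM at 8 weeks and 5.94 ± 1.4 CPM at 16 weeks. Of 16 genes of the endoplasmic reticulum and integrated stress response, 7 rose and 1 fell at 8 weeks (camera adjusted p = 0.0541, but under 0.05 without chow replicate 4, 8-week replicate 3 or 5 or 16-week replicate 7, range 0.02 to 0.57) and 4 rose and 1 fell at 16 weeks (median -0.00 but mean 0.76, 0.52 in the median with total counts alone, camera adjusted p = 0.597). Trib3, a pseudokinase induced by amino acid stress, rose from 2.67 ± 0.923 to 51.5 ± 18.02 and 68.3 ± 30.1 CPM. Between 8 and 16 weeks 1 NRF2 target rose (median -0.01 but 0.37 with total counts alone, camera adjusted p = 0.6), and 2 stress response genes fell, 1 adjusted over the list alone and 9 without replicate 3 of the 8-week group (median -0.36, camera adjusted p = 0.0188, and adjusted p = 0.402 with an estimated correlation). p53 targets and senescence genes rose in 4 of 14 cases (7 without replicate 3 of the 8-week group) and fell in 1 at 8 weeks, and rose in 9 and fell in 1 at 16 weeks (camera adjusted p = 0.293 and 0.101), with 1 rise and 1 fall between them, 1 rise and 0 falls adjusted over the list alone (0.262). Phlda3, a p53 target, rose from 1.16 ± 0.6 to 9.14 ± 7.54 and 11.1 ± 2.76 CPM.

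Fetal and tumour-associated liver genes rose in 5 of 10 cases at 8 weeks (camera adjusted p = 0.0305, but 0.0511 without replicate 3 of the 8-week group, range 0.0114 to 0.57, and adjusted p = 0.417 with an estimated correlation) and in 9 at 16 weeks (median 2.69, camera adjusted p = 0.000873, and adjusted p = 0.195 with an estimated correlation). Between 8 and 16 weeks 6 rose, and 7 adjusted over the list alone (camera adjusted p = 0.00159, and adjusted p = 0.264 with an estimated correlation). Afp, the fetal albumin-like protein, rose from 0.8 ± 0.225 to 5.39 ± 2.4 CPM at 8 weeks, and Ly6d, a surface antigen, from 1.1 ± 0.565 to 51.0 ± 49.4 and 90.2 ± 48.2 CPM. Circadian clock genes rose in 2 and fell in 8 of 13 cases at 8 weeks, with 9 falls adjusted over the list alone (median -1.03, camera adjusted p = 0.0257, and adjusted p = 0.417 with an estimated correlation). At 16 weeks 3 rose and 6 fell (camera adjusted p = 0.0655). Nr1d1, a repressor of the clock, rose from 5.16 ± 1.95 to 48.5 ± 31.1 and 45.4 ± 15.6 CPM, and Cry1 fell from 55.7 ± 6.82 to 16.3 ± 3.84 and 14.0 ± 2.35 CPM. The hour at which the livers were taken is not in the labels. Between 8 and 16 weeks edgeR called 0 of the 13 clock genes (median -0.01 but 0.38 with total counts alone, camera adjusted p = 0.944).

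The collagens score (mean log2 CPM over the list) was set against the scores of 6 other lists within each CDA-HFD group, 12 relations over 8 livers each, with exact two-sided permutation tests whose smallest possible p is 5e-05. By Pearson's r 0 of 12 passed the adjustment, with 4 at an unadjusted p under 0.05, and by Spearman's rho 2 passed. At 16 weeks livers with more collagen transcripts had more cell cycle transcripts (r = 0.812, permutation p = 0.0158, adjusted 0.101, and rho = 0.905, permutation p = 0.00456, adjusted 0.0434). At 8 weeks they had fewer transcripts of hepatocyte secreted proteins (r = -0.61, permutation p = 0.105, adjusted 0.18, and rho = -0.881, permutation p = 0.00724, adjusted 0.0434). Without the 2 livers farthest from the median score these became r = 0.767 (permutation p = 0.0708) and rho = 0.8286 (p = 0.0583) for the cell cycle and r = -0.522 (permutation p = 0.315) and rho = -0.8286 (p = 0.0583) for secreted proteins. Neither passed over those 6 livers. With the median over list members in place of the mean, cell cycle (rho = 0.619, permutation p = 0.115, adjusted 0.276) and secreted proteins at 8 weeks (rho = -0.5, permutation p = 0.216, adjusted 0.37) did not pass, and bile duct cell markers at 16 weeks did (rho = 0.952, permutation p = 0.00114, adjusted 0.0137). At 16 weeks, with the mean, bile duct cell markers (r = 0.747, permutation p = 0.0309, adjusted 0.106, and rho = 0.714, adjusted 0.167) and scar-associated macrophage markers (r = 0.739, permutation p = 0.0355, adjusted 0.106) did not pass the adjustment, nor did hepatocyte secreted proteins (r = -0.794, permutation p = 0.0169, adjusted 0.101).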
